A study of Homo sapiens with 6 samples.

How the data were processed

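Transcript abundance was measured by RNA sequencing in 6 libraries of NOMO-1 cells, 2 each of control, METTL16-knockout and METTL16-rescue cells. Per the labels' protocols, cells that overexpressed an empty vector or METTL16 were transduced with virus carrying a guide RNA, and were selected with puromycin at 2 µg/ml for 1 to 2 weeks. Per the labels' protocols, total RNA was extracted with QIAzol, ribosomal RNA was removed with Ribo-Zero, and stranded libraries were made with a TruSeq kit and sequenced on a HiSeq 2500. Per the submitters' processing notes, reads were aligned with STAR to GRCh38 and quantified with RSEM. No version of these tools is stated there.

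The deposited table gives 1 RSEM abundance per gene and library, called the signal here, since no header states whether it is TPM or FPKM. The values were used as the authors deposited them. The table held 15059 genes, no value of 0, and no column that could not be matched to a sample. Its minimum was near 0.1 in every library, which is a filter or floor that no source states. The genes stood in the order of the ratio of knockout to control (Spearman's rho of 1 across genes), and 80 of them carried values identical to those of another gene. Low values lay near multiples of 0.01 times a factor that differed between libraries, 0.892 to 1.096, and that changed with the level. A rescaling after rounding would leave such steps, and no source states one. Symbols were matched to GENCODE release 29, which gave coordinates for 13785 genes, of which 12254 were protein coding.

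No read totals are stated in the labels or the processing notes, so depth was estimated from the table. For transcripts of up to 400 nt and values under 4.5 reads, the signal times the length less 50 nt fell on whole multiples of 1 step per library, with 77 to 88 genes used per library. Between 90.6% and 97.6% of these values lay within 0.15 of a whole number, where chance gives 30% for a step fixed beforehand. The step was chosen for the best match in these same values, so the share by chance is higher than that. A signal of 1 then stands for 46.1 to 49.7 reads over 2000 nt and 22.4 to 24.2 reads over 1000 nt. Most small nucleolar RNAs and microRNA precursors rest on far fewer reads at the same signal, and their values carry large counting error.

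Groups came from the labels. The rule fixed for the test named TPM, FPKM, RPKM, CPM or counts and not an abundance of unstated kind, and the branch for normalized values was used. Genes with a signal of at least 1 in at least 2 libraries were kept, 12734 of them, and 2325 were left out. limma 3.58.1 in R 4.3.3 was run with a trend on log2(signal + 1), with all 6 libraries in 1 fit (3 residual and 11.0 prior degrees of freedom), and adjusted p is the Benjamini-Hochberg value over all genes tested, with a threshold of 0.05. The 3 comparisons were knockout minus control, rescue minus knockout and rescue minus control. Every adjusted p for a gene is from limma, two-sided. Adding 1 shrinks the log2 change of genes of low signal. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

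Gene lists, 32 in number, were written by hand before the data were examined, as were the test, its alternatives and the rule for named genes. Of these, 29 had enough tested members. Mitochondrially encoded messenger RNAs had 0 genes in the table, erythroid and megakaryocytic markers had 5 with 2 tested, and epithelial and embryonic kidney markers had 4 with 1 tested. Lists were tested with camera at the preset correlation of 0.01, which compares a list with all other genes. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move 1 way on balance and compares them with no other genes. Camera adjusted p were corrected over the lists of a comparison. With an estimated correlation no list passed in any comparison. These estimates, from 3 residual degrees of freedom, ran from 0.24 for interferon response to 0.75 for cholesterol and fatty acid synthesis. At 0.49 the histones, all 16 of them fallen in knockout, had an adjusted p of 0.898. Failing this test therefore does not show that a list was unchanged.

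Named genes were METTL16, MAT2A, BCAT1 and BCAT2, then up to 8 risen and 8 fallen genes per comparison with the largest absolute log2 change among those past 0.05 with non-overlapping libraries, a mean of at least 5 in the higher group and a symbol. Added to these were the 6 per direction with the largest changes that moved back in rescue, and up to 4 members per described list with the smallest p. Any other gene named is said to have been looked up after the values were seen. A gene moved back when it passed 0.05 in knockout against control and in rescue against knockout with opposite signs. The rescue cells were a parallel group that overexpressed METTL16 before the guide was introduced, so the term describes a difference between groups and no course in time. Chance values for that count came from 100 simulated tables with unchanged groups.

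The fit was tested on simulated data with 12734 genes and 50 genes changed per size. In the simulated knockout comparison it recovered 18.0% of genes changed by 0.25 on the log2 scale, 94.0% of those changed by 0.5, and 100% of those changed by 1 or 2. For rescue against knockout these shares were 26.0%, 96.0% and 100%, and for rescue against control 30.0%, 90.0%, 98.0% and 100%. The changed genes all had a mean log2(signal + 1) above 2, and the change was added on that scale. Recovery in genes of lower signal was not measured. False calls were 13 of 169, 19 of 180 and 13 of 172 in the 3 comparisons, and 9, 15 and 9 of these were short RNAs. Without short RNAs they made up 2.56%, 2.45% and 2.52% of calls. The data gave 5056, 4004 and 36 calls in these comparisons, and the cut-off of the adjusted p depends on that number. Noise was drawn gene by gene from the fitted spread, with no shift of a whole library. Shares recovered and falsely called may therefore differ in the data.

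Replicate numbers are shared between groups. Correlations of the deviations of libraries with the same number were -0.011 for control and knockout, -0.048 for control and rescue and 0.10 for knockout and rescue, so the numbers were not taken as pairs. Alternatives were quantile normalization, centring on the median log ratio, no filter, a mean signal of at least 5, limma without a trend and with robust variance, pseudocounts of 0.1 and 5, only the 2 groups compared, a replicate block, each library left out, an absolute log2 change of at least 1, and protein-coding genes without histones. Where a library was left out, its lone partner was assumed to vary like the other groups. Transcript isoforms, splicing and methylation sites were not analysed here. Values of some single list members are not reported here.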

Results

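Total RNA was sequenced from NOMO-1, a human acute myeloid leukaemia cell line, in 3 groups of 2 libraries each. Control cells carried a non-targeting guide RNA and an empty vector, knockout cells carried a guide against METTL16 and the empty vector, and rescue cells carried the same guide in cells that had first been made to overexpress METTL16. METTL16 is an RNA N6-adenosine methyltransferase known to act on the U6 small nuclear RNA and on the messenger RNA of MAT2A, the enzyme that makes S-adenosylmethionine. The table held 15059 genes with 1 abundance value per library, called the signal here. The signal summed over all genes was 668903 and 619472 in the control libraries, 649342 and 597160 in the knockout libraries, and 680458 and 681928 in the rescue libraries. The 4 most abundant RNAs, RN7SL1, SNORD3A, RN7SK and RN7SL2, made up 32.7% to 37.7% of these sums. No read totals are stated in the sources used here. Spacing of the values of short RNAs put a signal of 1 at 46.1 to 49.7 reads for a transcript of 2000 nt.

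Across genes, which are not independent replicates, the 2 libraries of a group correlated with Pearson's r of 0.997 in control, 0.996 in knockout and 0.997 in rescue on the log2 scale. The first principal component held 64.2% of the variance and separated the knockout libraries, at 23.3 and 19.95, from the control libraries, at -13.0 and -14.7, with the rescue libraries at -7.89 and -7.71. Control replicate 2 stood apart on the second component (12.7% of the variance) at -13.1, and its values lay below the rest, with a median log2 deviation of -0.12 where the other libraries lay between 0.0044 and 0.047. Nothing in the labels states that replicates are separate cultures, so p-values measure only the spread between these libraries.

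METTL16 itself (ENSG00000127804, chromosome 17, 2405562 to 2511891, minus strand, GRCh38) was lowest in the knockout libraries. Its signal was 9.76 ± 0.188 (SD, n = 2) in control, 5.94 ± 0.154 in knockout and 12.2 ± 0.123 in rescue. Knockout libraries thus held 0.609 of the control level, a log2 change of -0.63 (SE 0.082, adjusted p = 4.76e-05). An edit that disrupts a protein need not lower its transcript, and no source used here states whether reads of the introduced METTL16 were counted. The rescue libraries lay 0.93 above knockout on the log2 scale (adjusted p = 3.18e-06). They stood at 1.25 times the control level, a difference that did not pass the test (log2 0.30, adjusted p = 0.175, and 0.0462 to 0.624 over the alternatives).

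The METTL16 target MAT2A (chromosome 2, 85539165 to 85545280, plus strand) fell in knockout and rose in rescue. Its signal was 136 ± 6.06 (SD, n = 2) in control, 77.9 ± 0.353 in knockout and 136 ± 3.01 in rescue, a log2 change of -0.80 in knockout against control (adjusted p = 2.00e-07) and 0.79 in rescue against knockout (adjusted p = 3.58e-07). BCAT1 (chromosome 12, 24810022 to 24949459, minus strand), the cytosolic branched-chain aminotransferase, had a signal of 21.7 ± 1.07 in control, 14.8 ± 0.346 in knockout and 22.2 ± 1.17 in rescue. It fell by 0.53 on the log2 scale in knockout (adjusted p = 8.57e-05) and rose by 0.56 in rescue (adjusted p = 0.000102). BCAT2 (chromosome 19, 48795062 to 48811029, minus strand), the mitochondrial form, had a signal of 27.1 ± 2.77 in control, 12.7 ± 0.778 in knockout and 25.4 ± 0.276 in rescue. Its log2 change was -1.04 in knockout against control (adjusted p = 5.16e-07) and 0.95 in rescue against knockout (adjusted p = 2.11e-06). Between rescue and control none of these 3 genes passed the test, with adjusted p of 0.997 for MAT2A, 0.910 for BCAT1 and 0.708 for BCAT2.

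**Figure D1:**
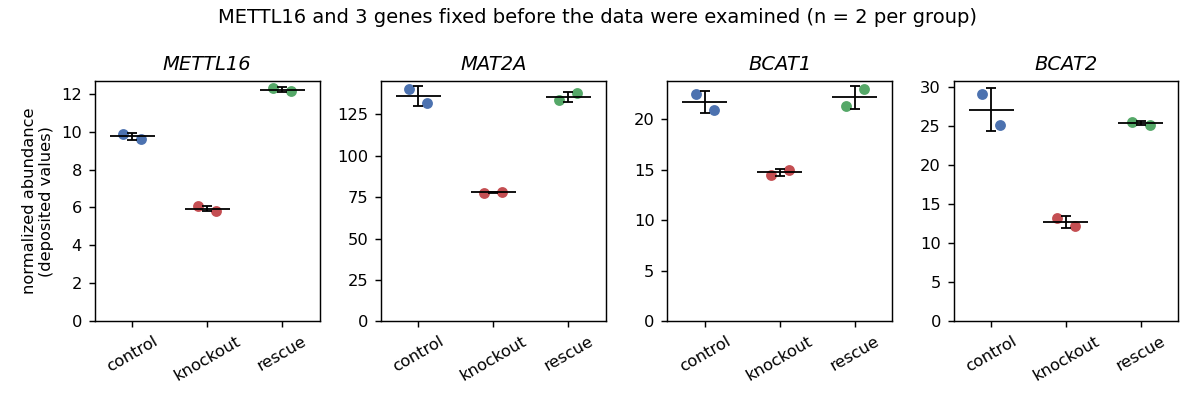
Signal of METTL16, MAT2A, BCAT1 and BCAT2 in control, knockout and rescue cells, with 1 dot per library, a line at the mean and a bar for the SD (n = 2). In each panel both knockout libraries lie below the control and the rescue libraries.

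The comparison of knockout with control asked which transcripts differed between cells with the guide against METTL16 and control cells. The largest rises under the naming rule included SLPI, S100A8 and CTSG. CTSG, which encodes the neutrophil granule protease cathepsin G, went from 314 ± 13.6 (SD, n = 2) in control to 1352 ± 16.8 in knockout, 4.30 times the control level (log2 2.10, adjusted p = 7.23e-12). Of the fixed lists, 25 of 31 genes of myeloid maturation rose, while all 16 replication-dependent histones and 18 of 27 genes of the ATF4 and amino acid response fell. At an adjusted p of 0.05, 3333 genes rose and 1723 fell among 12734 tested, and 81 and 22 of them changed at least 2-fold.

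Of the 31 measured genes of myeloid maturation, 25 rose, 1 fell and 5 did not pass the test, with a median log2 change of 0.57 (camera, adjusted p = 6.85e-12). The adjusted p was 0.898 with an estimated correlation. Adjusted over the list alone, the counts were again 25 and 1. SLPI, an inhibitor of neutrophil serine proteases outside this list, rose from 3.29 ± 0.178 to 20.5 ± 0.0519 (log2 2.33, adjusted p = 9.55e-10). S100A8, a calcium-binding protein of neutrophils and monocytes, rose from 5.29 ± 0.105 to 28.9 ± 2.31 (log2 2.25, adjusted p = 9.55e-10). ELANE, which encodes neutrophil elastase, rose by 1.47 and LYZ, which encodes lysozyme, by 1.42 on the log2 scale. Also outside this list, RNASE3, a ribonuclease of eosinophil granules, rose by 1.58, and FPR1, the receptor for formylated bacterial peptides, by 1.72. Nor were the next 3 genes members. DHRS9, a short-chain dehydrogenase, rose by 1.89, TP53INP2, a protein of autophagy, by 1.80, and CCNA1, a cyclin of the male germ line also expressed in myeloid leukaemia, by 1.59. The 1 fallen member of the list was CEBPB, a transcription factor of myeloid cells, at -0.24 (adjusted p = 0.0219), a gene looked up after the count was seen.

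**Figure D2:**
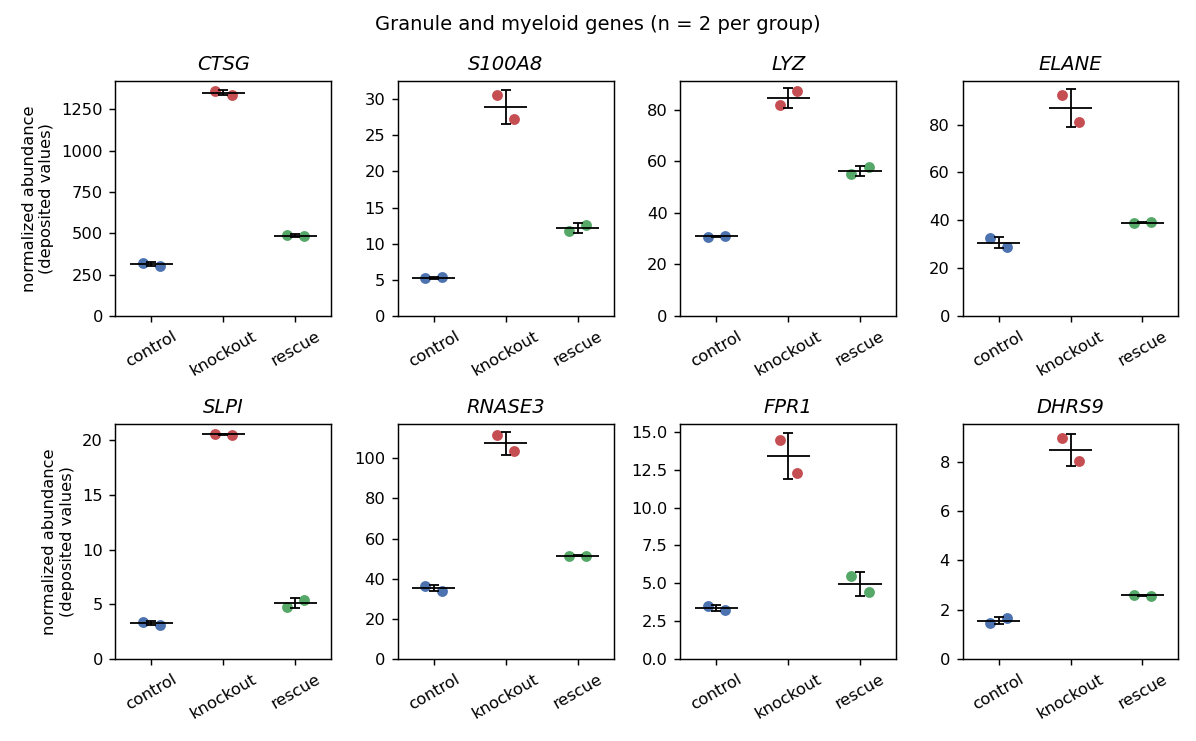
Signal of 8 granule and myeloid genes in control, knockout and rescue cells, with 1 dot per library, a line at the mean and a bar for the SD (n = 2). CTSG had means of 314 in control, 1352 in knockout and 487 in rescue.

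In the list of ATF4 targets and the amino acid response, 18 of 27 measured genes fell and none rose (median log2 -0.29, camera adjusted p = 1.13e-11, adjusted p = 0.898 with an estimated correlation). Adjusted over the list alone, 21 fell and none rose. The examples were PSAT1, an enzyme of serine synthesis, at -0.76, TRIB3, a pseudokinase induced by stress, at -0.81, SHMT2, the mitochondrial serine hydroxymethyltransferase, at -0.76, and DDIT4, an inhibitor of mTORC1 signalling, at -0.80. Among serine, glycine and folate one-carbon enzymes 9 of 16 fell and none rose (median -0.19, camera adjusted p = 7.05e-05, adjusted p = 0.898 with an estimated correlation), with the same counts adjusted over the list alone. PSAT1, SHMT2 and MTHFD1L (-0.64) were among the members with the smallest p. The methionine and S-adenosylmethionine cycle had 8 of 19 genes fallen and 2 risen (median -0.12, camera adjusted p = 0.00607, adjusted p = 0.927 with an estimated correlation), with the same counts adjusted over the list alone. CTH, which makes cysteine from cystathionine, fell by 0.95, and AMD1, which commits S-adenosylmethionine to polyamine synthesis, rose by 0.38. The other risen member was AHCYL2 (0.32), looked up after the count was seen.

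Branched-chain amino acid catabolism had 4 of 26 genes fallen and 2 risen, and the same adjusted over the list alone (median -0.069, camera adjusted p = 0.0319, adjusted p = 0.927 with an estimated correlation). The fallen members included BCAT2, BCAT1 and PCCB, a subunit of propionyl-CoA carboxylase, at -0.58, and the risen ones included MUT, which encodes methylmalonyl-CoA mutase, at 0.40. MCCC2 (-0.22) and IVD (0.29), enzymes of leucine breakdown looked up after the counts were seen, made up the rest. Transporters of large neutral amino acids and glutamine had 6 of 13 fallen and 3 risen, and the same adjusted over the list alone (median -0.12, camera adjusted p = 0.0499, adjusted p = 0.927 with an estimated correlation). SLC7A11, the cystine and glutamate exchanger, was at -0.53 and SLC1A4, a carrier of small neutral amino acids, at 0.34, and SLC25A44, a mitochondrial carrier of branched-chain amino acids, at 0.52. The call for branched-chain catabolism was lost without control replicate 1 (camera adjusted p = 0.0847, median 0.022) and without knockout replicate 2 (0.0682), and with a mean signal of at least 5 (0.073). That for the transporters was lost after quantile normalization (0.0617) and without control replicate 2 (0.0632), knockout replicate 1 (0.0726), knockout replicate 2 (0.134), rescue replicate 1 (0.0947) or rescue replicate 2 (0.0945). It was also lost without a filter (0.0861), with a mean signal of at least 5 (0.0622), without a trend (0.0793), with a pseudocount of 0.1 (0.0508), with only the 2 groups in the fit (0.0946), with the replicate block (0.0679) and for protein-coding genes (0.0505).

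Cytoplasmic ribosomal proteins had 30 of 53 genes fallen and 2 risen, and the same adjusted over the list alone (median -0.15, camera adjusted p = 1.52e-11, adjusted p = 0.898 with an estimated correlation). RPS12 fell from 953 ± 37.4 to 539 ± 6.62 and RPL13A from 542 ± 19.7 to 330.0 ± 10.7. RPS15 (0.21) and RPL10A (0.19), looked up after the count was seen, were the 2 that rose. After quantile normalization the group's direction was lost, with 11 risen, 15 fallen, a median of -0.0081 and a camera adjusted p of 0.824. MYC targets and ribosome biogenesis factors had 15 of 30 fallen and 2 risen, and 17 and 2 adjusted over the list alone (median -0.17, camera adjusted p = 4.55e-05, adjusted p = 0.898 with an estimated correlation). NOLC1, a nucleolar chaperone, fell by 0.60 and MYC, the growth transcription factor, by 0.49.

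All 16 measured replication-dependent histones fell, and all 16 did adjusted over the list alone, with a median log2 change of -0.47 (camera adjusted p = 3.64e-14, adjusted p = 0.898 with an estimated correlation). After quantile normalization 14 fell and 1 rose. The examples were HIST2H2AC at -0.58 and the linker histone HIST1H1C at -0.53. Nuclear long non-coding RNAs had 7 of 13 fallen and 1 risen, and the same adjusted over the list alone (median -0.32, camera adjusted p = 0.000626, adjusted p = 0.898 with an estimated correlation). MALAT1, which sits in nuclear speckles, went from 1058 ± 48.2 to 469.6 ± 6.15, and NORAD, which binds PUMILIO proteins, rose by 0.40. DNA repair genes had 8 of 30 fallen and none risen, and 5 fallen adjusted over the list alone (median -0.087, camera adjusted p = 0.00146, adjusted p = 0.927 with an estimated correlation).

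The unfolded protein response had 17 of 25 genes risen and 1 fallen, and 18 and 1 adjusted over the list alone (median 0.35, camera adjusted p = 0.000109, adjusted p = 0.898 with an estimated correlation). CALR, a chaperone of the endoplasmic reticulum, rose by 0.84 and CRELD2, a secreted stress protein, by 1.04, while DDIT3, the pro-apoptotic factor CHOP, was at -0.90. Immediate early and heat shock genes had 15 of 23 risen and none fallen, and the same adjusted over the list alone (median 0.34, camera adjusted p = 0.000626, adjusted p = 0.898 with an estimated correlation). HSPA1A, an inducible HSP70, rose by 1.09 and DNAJB1, its co-chaperone, by 0.80. Interferon response genes had 14 of 24 risen and 2 fallen, and the same adjusted over the list alone (median 0.28, camera adjusted p = 0.0129, adjusted p = 0.898 with an estimated correlation), with IRF9 at 0.74 and IRF1 at 0.70, both transcription factors of that response. The interferon call was lost without control replicate 1 (camera adjusted p = 0.052), without knockout replicate 2 (0.0568) and with a mean signal of at least 5 (0.117).

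**Figure D3:**
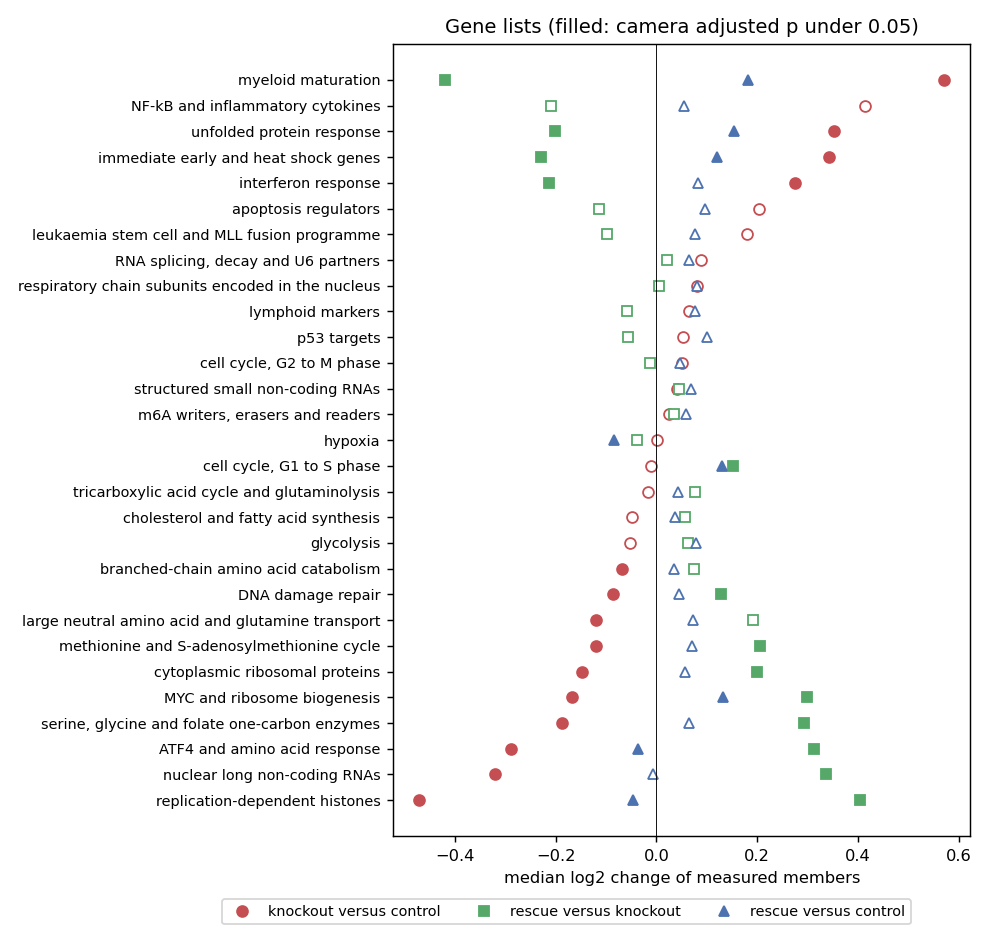
Median log2 change of each of the 29 tested gene lists on the horizontal axis, for knockout against control, rescue against knockout and rescue against control. Filled symbols mark a camera adjusted p under 0.05 at the preset correlation, and myeloid maturation stands at 0.57 in knockout, -0.42 in rescue against knockout and 0.18 in rescue against control.

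By fry 10 lists passed in knockout, namely myeloid maturation (adjusted p = 0.0174), histones (0.0228), ATF4 targets, the unfolded protein response, immediate early genes and interferon (0.0289 each), one-carbon enzymes and NF-kB genes (0.0438 each), and ribosomal proteins and nuclear RNAs (0.0454 each). MYC targets (0.0673), the methionine cycle (0.168), DNA repair (0.204), transport (0.284) and branched-chain catabolism (0.319) passed camera but not fry.

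The other 15 lists did not pass camera, with adjusted p from 0.0600 to 0.852. NF-kB and inflammatory cytokine genes had 11 of 19 risen and 2 fallen, apoptosis regulators 14 of 29 risen and 4 fallen, and the leukaemia stem cell and MLL fusion programme 10 of 23 risen and 2 fallen. Adjusted over the list alone these became 11 and 3, 16 and 4, and 13 and 2. CASP1, an inflammatory caspase, rose by 1.15 and MEIS1, a homeobox partner of HOXA9, by 0.66. The m6A writers, erasers and readers had 5 of 25 risen and 2 fallen, with the readers IGF2BP2 at -0.96 and IGF2BP3 at -0.58. Respiratory chain subunits (13 of 51 risen, 8 fallen), the tricarboxylic acid cycle and glutaminolysis (8 and 8 of 30), glycolysis (3 and 5 of 21), hypoxia (2 and 4 of 17) and cholesterol and fatty acid synthesis (5 and 7 of 26) moved both ways. Adjusted over the list alone the first became 13 and 9 and the next 9 and 9, and the other counts here held. NDUFS3, a subunit of complex I, fell from 64.6 ± 2.40 to 24.5 ± 0.735 and PFKL, a phosphofructokinase, from 27.3 ± 1.95 to 12.4 ± 0.648. The remaining lists had 4 risen and 7 fallen of 35 for G1 to S phase (4 and 5 adjusted over the list alone), 7 and 5 of 36 for G2 to M phase, 9 and 4 of 23 for p53 targets, 8 and 3 of 28 for splicing and U6 partners, 3 and 2 of 26 for structured small RNAs and 3 and 1 of 8 for lymphoid markers, with the same counts adjusted over the list alone for the last 5. The median was above 0 and the mean below 0 for m6A genes, respiratory chain and hypoxia, and camera pointed down where median and mean were above 0 for G2 to M phase and small RNAs.

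Under the naming rule, which ranks by log2(signal + 1), the largest falls in protein-coding genes were in C17orf49, THOC3 and NDUFS3. C17orf49, a chromatin-associated protein, went from 15.4 ± 1.93 to 3.46 ± 1.11 (log2 -1.89, adjusted p = 3.04e-07). THOC3, a subunit of the THO messenger RNA export complex, was at -1.40 (adjusted p = 4.30e-08) and NDUFS3 at -1.37 (adjusted p = 3.15e-09). RNASEK-C17orf49, an entry that joins C17orf49 to RNASEK and was looked up after the values were seen, was called as risen in knockout. Of its rise, 49.2% was left in rescue. Whether reads were assigned differently between it and C17orf49 was not tested. The long non-coding RNA LINC01226 was at -1.37. Some single small RNAs also met the naming rule. SNORD16, a small nucleolar RNA, was at -1.85 (adjusted p = 4.40e-07). SNORD1C was at -1.39 (adjusted p = 0.00461), a call lost without control replicate 1 (adjusted p = 0.0829) and without control replicate 2 (adjusted p = 0.157). The copies MIR3687-1 and MIR3687-2, which carry identical values, were at -4.96 (SE 1.14, adjusted p = 0.00365), with a signal of 511 ± 329 in control and 56.2 ± 78.1 in knockout. Their call was lost without control replicate 1 (adjusted p = 0.148) and without control replicate 2 (adjusted p = 0.0787). After quantile normalization the adjusted p was 0.0556 for MIR3687-1 and 0.0573 for SNORD1C, and without a trend it was 0.217 and 0.222.

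The division between risen and fallen genes in knockout depended on scaling. Of the called genes, 65.9% rose with the values as deposited. With each library centred on its median log ratio, 3134 rose and 3225 fell, and without control replicate 2 the counts were 2377 and 2257. The total was 5346 without control replicate 1, 4634 without control replicate 2 and 3363, 2065 of them risen, without knockout replicate 1.

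The comparison of rescue with knockout asked which transcripts differed between cells that carried the guide with and without prior overexpression of METTL16. Of the fixed lists, 23 of 31 genes of myeloid maturation fell, while all 16 histones and 17 of 27 genes of the ATF4 and amino acid response rose. CTSG went from 1352 ± 16.8 (SD, n = 2) to 487 ± 7.19 (log2 -1.47, adjusted p = 1.01e-09) and SLPI from 20.5 ± 0.0519 to 5.11 ± 0.444 (log2 -1.82, adjusted p = 3.67e-08). C17orf49 rose from 3.46 ± 1.11 to 14.4 ± 1.10 and THOC3 from 11.1 ± 0.800 to 29.5 ± 0.813. Of 12734 genes, 1982 rose and 2022 fell, and 21 and 35 of them changed by at least 1 in log2(signal + 1). Risen and fallen genes were 1513 and 1119 without knockout replicate 1, 1309 and 1449 without knockout replicate 2, 1373 and 1251 without rescue replicate 1, and 1154 and 1330 without rescue replicate 2.

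Of 31 myeloid maturation genes 23 fell and 1 rose (median log2 -0.42, camera adjusted p = 6.79e-12). CEBPB was the 1 that rose (0.31). Outside the list, DHRS9 (-1.40), TP53INP2 (-1.43) and FPR1 (-1.27) were among the largest falls in any gene. Cytoplasmic ribosomal proteins had 42 of 53 risen and none fallen (median 0.20, camera adjusted p = 2.43e-14), but 14 risen and 5 fallen after quantile normalization, with a camera adjusted p of 0.245. All 16 histones rose (median 0.40, camera adjusted p = 2.80e-12). MYC targets and ribosome biogenesis had 19 of 30 risen, ATF4 and the amino acid response 17 of 27, one-carbon enzymes 8 of 16, DNA repair 10 of 30 and the methionine and S-adenosylmethionine cycle 10 of 19, with none fallen in these 5 lists and camera adjusted p from 3.25e-09 to 0.00290. MYC rose by 0.73, NOLC1 by 0.70, MTHFD1L by 0.65 and CTH by 0.83 on the log2 scale. The cell cycle list for G1 to S phase, which had not passed in knockout, had 12 of 35 risen and 1 fallen (median 0.15, camera adjusted p = 0.000109), with CCND2, a D-type cyclin, at 0.97 and MCM4, a replicative helicase subunit, at 0.52. Whether its change differed between the comparisons was not tested. With an estimated correlation the adjusted p of every list in this comparison was 0.810 or more. By fry 7 lists passed, myeloid maturation and histones (adjusted p = 0.0320 each), ATF4 targets, MYC targets and ribosomal proteins (0.0360 each), one-carbon enzymes (0.0420) and nuclear RNAs (0.0499). The other 6 lists that passed camera did not pass fry, with adjusted p of 0.0640 for interferon and immediate early genes, 0.0973 for the unfolded protein response, and 0.105 for G1 to S phase, the methionine cycle and DNA repair.

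Nuclear long non-coding RNAs had 8 of 13 risen and 1 fallen (median 0.34, camera adjusted p = 0.000267), with MALAT1 at 0.95. The unfolded protein response had 12 of 25 fallen and 1 risen (median -0.20, camera adjusted p = 0.00139), immediate early and heat shock genes 11 of 23 fallen and 2 risen (median -0.23, camera adjusted p = 0.00297), and interferon response genes 10 of 24 fallen and 2 risen (median -0.21, camera adjusted p = 0.0153). These calls too were lost with an estimated correlation, at an adjusted p of 0.810 or more, and that of the interferon list was lost after quantile normalization (camera adjusted p = 0.0556), with a mean signal of at least 5 (0.123), without knockout replicate 2 (0.0768) and without rescue replicate 2 (0.056). CALR was at -0.50 and HSPA1A at -0.99. Against the direction of their lists, NORAD was at -0.25 and DDIT3 at 0.76. The mitochondrial chaperones HSPD1, at 0.20, and HSPE1, at 0.16, also rose against their list and were looked up after the counts were seen. Adjusted over the list alone, counts of risen and fallen genes were 1 and 23 for myeloid maturation, 46 and 0 for ribosomal proteins, 16 and 0 for histones, 21 and 1 for MYC targets, 20 and 0 for ATF4, 10 and 0 for one-carbon enzymes, 10 and 0 for DNA repair, 11 and 1 for the methionine cycle, 13 and 1 for G1 to S phase, 8 and 1 for nuclear RNAs, 1 and 12 for the unfolded protein response, 2 and 12 for immediate early genes and 3 and 10 for interferon. The other 16 lists had camera adjusted p from 0.0507 to 0.964, among them transport with 7 risen and 2 fallen and branched-chain catabolism with 4 and 1, the same counts as adjusted over the list alone. Median and mean differed in sign for splicing, G2 to M phase and hypoxia.

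Several small RNAs met the naming rule in this comparison. MIR616 (0.947 to 5.54), SNORD34 (5.02 to 15.6), MIRLET7D (1.69 to 5.61) and SNORD143 (4.67 to 12.8) rose, as did the MIR3687 copies (log2 4.35, adjusted p = 0.0102). SNORD45C (11.6 to 1.49), SNORD116-14 (22.3 to 7.30) and SNORA22 (8.44 to 3.70) fell. The calls of MIR3687-1, SNORD116-14 and SNORA22 were lost without control replicate 1, with adjusted p of 0.0883, 0.0601 and 0.122, and without control replicate 2, with 0.0883, 0.0601 and 0.122. In the same order they were lost after quantile normalization (0.0899, 0.0601 and 0.121), with centred libraries (0.0764, 0.0540 and 0.107), without a trend (0.288, 0.256 and 0.326) and with only the 2 groups in the fit (0.0889, 0.0606 and 0.123). That of SNORA22 was also lost without rescue replicate 2, at 0.0733. Without a trend in limma SNORD34 and MIRLET7D lost theirs, at 0.189 and 0.0539.

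Of the 5056 genes changed in knockout, 3381 moved back in rescue. These were 1913 genes risen in knockout and lower in rescue than in knockout, 57.4% of the risen ones, and 1468 fallen in knockout and higher in rescue, 85.2% of the fallen ones. With centred libraries the shares were 78.0% and 79.9%. LILRA5, an activating receptor of myeloid cells, was among the genes that rose most and moved back (1.56, then -1.22), with CTSG, SLPI, TP53INP2, DHRS9 and FPR1. Among genes that fell and moved back were C17orf49, THOC3, NDUFS3 (-1.37, then 1.27) and API5, an inhibitor of apoptosis, which went from 53.1 ± 2.48 (SD, n = 2) to 21.99 ± 0.456 in knockout and 52.2 ± 0.552 in rescue. SNORD16 and SNORD1C did not pass the test in rescue against knockout, with log2 changes of 0.36 and 0.19, and the change of SNORD1C turned to -0.35 without knockout replicate 1 and -0.46 without rescue replicate 1. Independent lists of these sizes would share 529 and 268 genes. Both contrasts use the same knockout libraries, which alone gives opposite signs. Simulated data with unchanged groups gave 1.10 genes moved back on average and at most 6 in 100 draws. Few genes are called in such data, so this count is low by construction. It does not show what shared libraries give when 5056 genes are called in knockout. Data with the knockout changes kept and rescue equal to knockout were not simulated. The covariance of the fold changes across genes was -0.077, against -0.0049 in the simulation. The total was 2141 without knockout replicate 1 and 2250 without rescue replicate 2.

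**Figure D4:**
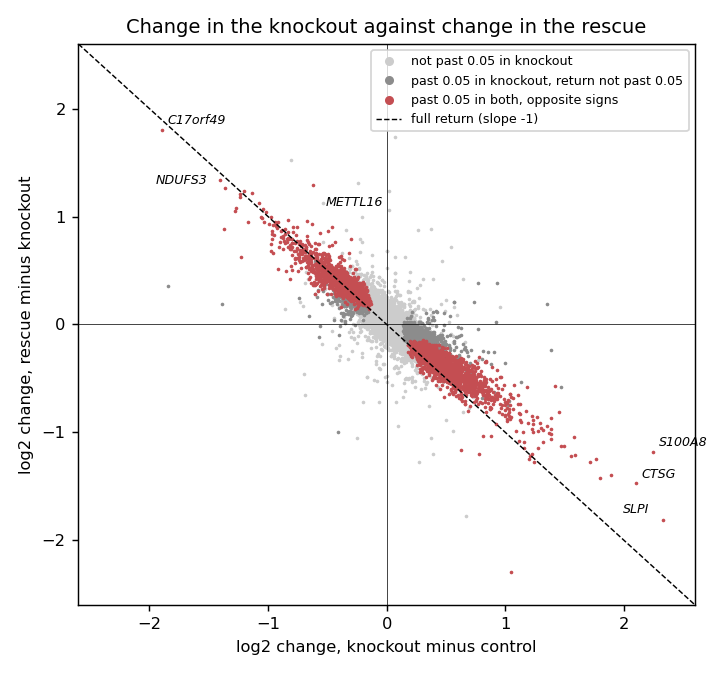
Each dot is 1 tested gene, with its log2 change in knockout against control on the horizontal axis and in rescue against knockout on the vertical axis, and the dashed line marks rescue equal to control. Colours separate genes past 0.05 in knockout alone from those past 0.05 in both with opposite signs, and 2 genes lie outside the plotted range.

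The comparison of rescue with control asked which transcripts differed between control cells and cells that overexpressed METTL16 and carried the guide. Of 31 genes of myeloid maturation 5 were above control, and most genes did not pass the test. S100A8 was at 12.2 ± 0.649 (SD, n = 2) against 5.29 ± 0.105 in control (log2 1.07, adjusted p = 1.57e-05), LYZ at 56.4 ± 1.98 against 31.0 ± 0.137 (log2 0.85, adjusted p = 7.45e-06) and CTSG at 487 ± 7.19 against 314 ± 13.6 (log2 0.63, adjusted p = 2.27e-05). At an adjusted p of 0.05, 29 genes rose and 7 fell. Centred libraries left 6 risen and none fallen, and the total was 23 without a filter, 225 with a mean signal of at least 5, 245 for protein-coding genes without histones, 288 with only the 2 groups in the fit and 382 with the replicate number as a block. At an unadjusted p under 0.05 there were 1463 genes with the values as deposited.

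Of 31 myeloid maturation genes 5 rose and none fell, and 15 rose adjusted over the list alone (median log2 0.18, camera adjusted p = 1.74e-12, adjusted p = 0.993 with an estimated correlation). The 5 were S100A8, LYZ, CTSG, S100A9, the partner of S100A8, at 0.64, and MNDA, a nuclear protein of myeloid cells looked up after the count was seen, at 0.42. The next lists by camera moved little, with 0 genes past the threshold in 6 of them. Medians were 0.13 for G1 to S phase and 0.13 for MYC targets, where 9 genes rose adjusted over the list alone, 0.12 for immediate early genes, where 5 did, -0.036 for ATF4 targets and -0.084 for hypoxia, where 2 genes each fell adjusted over the list alone, and -0.047 for histones. The unfolded protein response had 1 gene risen, CALR, and 11 adjusted over the list alone (median 0.15). Camera adjusted p of these 7 lists lay between 1.17e-06 and 0.00204, and all were 0.993 with an estimated correlation. The call for immediate early genes was lost without rescue replicate 1 (camera adjusted p = 0.122). By fry no list passed in this comparison, with adjusted p of 0.431 or more. The other 21 lists had camera adjusted p from 0.0548 to 0.968. Camera pointed down with median and mean above 0 for DNA repair, branched-chain catabolism, G2 to M phase, cholesterol, transport, lymphoid markers and one-carbon enzymes, since it compares a list with all other genes, whose median was 0.061.

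Small RNAs made up 17 of the 36 calls. MIR616, MIRLET7D, SNORD50B, SNORD18A, SNORD143 and SCARNA21 rose and SNORD16, SNORD42B and SNORA18 fell. SNORD50B went from an estimated 2.03 reads per library in control to 6.01 in rescue, and SNORD42B from 3.54 to 0.990. Without control replicate 1 calls were lost for SNORD16 (adjusted p = 0.0582), SNORD18A (0.0824), SNORD42B (0.0672), SNORD50B (0.0823), MIRLET7D (0.0982) and SNORA18 (0.0913). Without control replicate 2 they were lost for SNORD16 (0.156), SNORD42B (0.211), SNORD50B (0.472), MIRLET7D (0.411), SNORA18 (0.199), SCARNA21 (0.1001) and SNORD143 (0.067), and without rescue replicate 1 for SNORA18 (0.0654). Quantile normalization lost the calls of MIRLET7D, SCARNA21, SNORA18, SNORD16, SNORD18A, SNORD42B and SNORD50B, with adjusted p from 0.0511 to 0.225, and centring lost the same 7, from 0.0560 to 0.231. Without a trend all of these but SNORA18 were lost (0.116 to 0.566), and without a filter MIRLET7D (0.0612), SCARNA21 (0.0564), SNORA18 (0.123) and SNORD50B (0.149). SNORA18 was also lost with a pseudocount of 5 (0.0555) and SNORD50B with 0.1 (0.0543). MIR616 rose from 0.849 to 5.54 (log2 1.81, adjusted p = 7.45e-06), an estimated 1.02 to 6.25 reads. Of the 29 genes that rose here, 23 had also risen in knockout, where independent lists would share 7.59, and 3 of the 7 fallen had fallen there, against 0.947. The comparisons share the control libraries. Simulated tables with the knockout changes kept and rescue set equal to control, added after the result was seen, gave 2.6 calls shared in the same direction on average and at most 9 in 100 draws. The correlation of the 2 sets of fold changes across genes was 0.466, against 0.163 in these tables and 0.499 in tables where no group differed, and the covariance was 0.019, against 0.0049 in both. Both kinds of simulated table drew noise gene by gene and hold no shift of a whole library, such as the lower values of control replicate 2. A lower control library raises both comparisons together, so these tables cannot exclude it as a source of the shared rises. Counts of changed genes were 19 without control replicate 1, 8 without control replicate 2, 281 without knockout replicate 1, 278 without knockout replicate 2, 224 without rescue replicate 1 and 166 without rescue replicate 2.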

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

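No alternative given in this part was chosen after its result was seen. Over the alternatives other than a change of the list test, 1427 results for single genes stayed on their side of the threshold. Another 110 gained a call, 123 lost one and 2 reversed. A reversal was counted only where the main or the alternative result passed. The 1427 thus include changes of sign between uncalled results, such as BCAT1 in rescue against control, from -0.039 to 0.080. For lists the counts in the same order were 1315, 39, 26 and 0, with camera at the preset correlation throughout. A change of the list test is not among them. An estimated correlation lost all 14, 13 and 8 calls of the 3 comparisons, and fry lost 5, 6 and 8 of them and gained 1, 0 and 0. The 2 that reversed were SNORD1C in rescue against knockout, -0.35 without knockout replicate 1 and -0.46 without rescue replicate 1, where leaving out the partner libraries gave 0.72 and 0.84, with an estimated 4.10 and 9.37 reads in the knockout libraries and 11.9 and 4.27 in the rescue libraries. METTL16 in knockout ran from -0.71 to -0.43, with adjusted p up to 0.00166. MAT2A ran from -0.87 to -0.75, BCAT1 from -0.60 to -0.44 and BCAT2 from -1.14 to -0.86 there, and all were called throughout except where the change had to reach 1, which BCAT2 alone did. Limma-voom was not run, as the values are not counts. Depth may limit the small RNAs. Of 16 called between rescue and control, 12 had fewer than 10 estimated reads in the lower group. That share was not compared with short RNAs not called.

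After quantile normalization 3187 genes fell in knockout, 2509 fell there and were higher in rescue, and 19 rose and 14 fell in rescue against control. With centred libraries 3225 fell in knockout, 2577 fell there and were higher in rescue, and 6 changed in rescue against control, 6 risen and 0 fallen. Both scalings move the median change to near 0 by construction. Without a filter rescue against control gave 23 genes, 17 risen. A mean signal of at least 5 gave 225, 194 risen and 31 fallen, and protein-coding genes without histones gave 245, 222 risen and 23 fallen, and the cause was not tested. In the last of these METTL16 in rescue against control, at 0.30, passed with an adjusted p of 0.0462, where the alternatives ran from 0.0462 to 0.624. Without a trend 12 genes fell in rescue against control, and only the 2 groups compared gave 288, 217 risen and 71 fallen. The cause was not tested for these last changes.

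An absolute log2 change of at least 1 left 103 genes in knockout, 81 risen and 22 fallen, 56 in rescue against knockout, 21 risen and 35 fallen, and 10 in rescue against control, 6 risen and 4 fallen. It left 39 genes moved back, 25 risen first and 14 fallen first, and it dropped METTL16 at -0.63 and 0.93, all by construction. Camera with an estimated correlation called 0 lists in knockout, 0 in rescue against knockout and 0 in rescue against control, and fry called 10 in knockout, 7 in rescue against knockout and 0 in rescue against control. In knockout fry did not call MYC targets (adjusted p = 0.0673), the methionine cycle (0.168), DNA repair (0.204), transport (0.284) and branched-chain catabolism (0.319), which camera called, and it called NF-kB genes (0.0438), which camera did not, and the cause was not tested. With the replicate number as a block, 5475, 4477 and 382 genes changed in the 3 comparisons, the last as 299 risen and 83 fallen, and the cause was not tested.

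With single libraries left out, genes changed ran from 3363 (without knockout replicate 1) to 5346 (without control replicate 1) in knockout, with 2065 to 4127 risen and 1182 to 2257 fallen. In rescue against knockout they ran from 2484 (without rescue replicate 2) to 5030 (without control replicate 1), with 1154 to 2492 risen and 1119 to 2538 fallen. In rescue against control they ran from 8 (without control replicate 2) to 281 (without knockout replicate 1), with 6 to 213 risen and 1 to 73 fallen. Genes moved back ran from 2141 (without knockout replicate 1) to 3903 (without control replicate 2), with 1042 to 2420 risen first and 983 to 1941 fallen first. Lists passing camera numbered 11 to 13, 12 to 17 and 7 to 9 in the 3 comparisons. METTL16 ran from -0.66 to -0.61 in knockout, 0.91 to 0.95 in rescue against knockout and 0.28 to 0.31 in rescue against control. A left-out library leaves fewer samples, yet some counts rose above those of the fit with all 6 libraries. Among them was that of rescue against control without any 1 of the knockout or rescue libraries. The cause of these changes was not tested.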

Other observations

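The gene families described first, the tests on fallen genes, the test of the myeloid list's own changes after centring, the contrasts from separate libraries and the test without control replicate 2 on the share of risen genes were chosen only after the results were seen. Families were defined by symbol, and 15 were tested. Cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs with amino acids, had 10 of 20 genes fallen and 2 risen in knockout (median log2 -0.17, camera adjusted p = 8.62e-06, adjusted p = 0.924 with an estimated correlation), with LARS at -0.99 and IARS at -0.92. XPOT, the exporter of transfer RNAs from the nucleus, went from 91.2 ± 3.89 (SD, n = 2) in control to 37.2 ± 0.558 in knockout and 79.6 ± 1.96 in rescue. Nucleoporins had 10 of 20 fallen and 2 risen (median -0.19, camera adjusted p = 0.000712), translation initiation factors 16 of 52 fallen and 6 risen (median -0.082, camera adjusted p = 0.000712) and host genes of small nucleolar RNAs 7 of 18 fallen and 1 risen (median -0.20, camera adjusted p = 0.000201), each at an adjusted p of 0.924 with an estimated correlation. In rescue against knockout 12 synthetases, 11 nucleoporins, 22 initiation factors and 10 host genes rose, and 1, 0, 3 and 0 fell. By fry no family passed in any comparison, with adjusted p in knockout of 0.0847 for synthetases, 0.118 for nucleoporins and host genes and 0.405 for initiation factors. These genes were named after their values were seen.

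Lysosomal hydrolases and membrane proteins had 23 of 38 genes risen and 5 fallen in knockout (median 0.34, camera adjusted p = 0.000201) and subunits of the vacuolar ATPase, the proton pump of lysosomes, 12 of 20 risen and 1 fallen (median 0.23, camera adjusted p = 0.0136), both at an adjusted p of 0.924 with an estimated correlation. CD63, a lysosomal membrane protein also found on granules, rose by 0.74 and GLA, the lysosomal alpha-galactosidase, by 0.81. By fry the adjusted p was 0.0861 and 0.116. In rescue against knockout 21 and 8 of these genes fell, and 4 and 1 rose. Autophagy genes had 14 of 28 risen and 1 fallen, which did not pass camera (adjusted p = 0.0559). In rescue against knockout autophagy genes (9 fallen, 1 risen, adjusted p = 0.0454), proteasome subunits (11 risen, 1 fallen, adjusted p = 0.0454) and mitochondrial ribosomal proteins (19 risen, 4 fallen, adjusted p = 0.0494) passed camera, at an adjusted p of 0.786 or more with an estimated correlation. In knockout the other 8 families had adjusted p from 0.370 to 0.778, and for mitochondrial ribosomal proteins, proteasome subunits, ZNF genes, solute carriers and snoRNAs camera pointed down with median and mean above 0. In rescue against control the lysosomal genes (median 0.097, camera adjusted p = 0.00466) and proteasome subunits (median 0.10, camera adjusted p = 0.000478) passed camera above the other genes and ZNF genes below them (median 0.031, camera adjusted p = 0.00466), with no member past the threshold and an adjusted p of 1.00 with an estimated correlation. The other 12 families had camera adjusted p from 0.0730 to 0.999 there. By fry the smallest adjusted p was 0.0641 in rescue against knockout and 0.315 in rescue against control. Signs of the medians of the called families were kept under both scalings, except for ZNF genes in rescue against control, at -0.027 with centred libraries and -0.026 after quantile normalization.

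More genes rose than fell in knockout, 65.9% of those called. The share was 49.3% with centred libraries and 49.7% after quantile normalization, but these tests decide nothing, since both scalings set the median change to near 0. Without control replicate 2, whose values lie below those of the other libraries, it was 51.3%, and without control replicate 1 it was 77.2%. The excess of risen genes may therefore rest on 1 control library. Whether METTL16 loss raises more transcripts than it lowers stays open.

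Myeloid maturation genes lay above control in rescue, with a median log2 change of 0.18. Unequal scaling of libraries is argued against by the list's own changes after centring, with a median of 0.13, quartiles of 0.042 and 0.25, 25 of 31 members above 0 and 3 past the threshold, whereas the camera adjusted p of 1.72e-10 there decides nothing, since a shift common to all genes cancels in it. A share of rescue cells without the introduced METTL16 could leave a like part of every change. The median part left was 22.98% in 16 risen members (LYZ 47.5%, S100A9 32.5%, S100A8 29.2%, CTSG 16.6%, ELANE 14.8%) against 20.8% in 570 other risen genes. The difference was 2.15 percentage points (two-sided permutation test, p = 0.489). Quartiles were 17.4% and 30.1% in the members and 15.2% and 28.6% in the others. Medians alone were compared, so the test cannot show that single genes left a like part. Fallen genes leave a share of cells without the introduced METTL16 open. With the values as deposited, 9.37% was left in 277 of them against 20.9% in all 586 risen genes. These lay 11.5 points apart (permutation p = 1e-05, the smallest the resamples can give), past the bound of 10 points set for the test. With centred libraries 19.0% was left in fallen and 15.6% in risen genes, a difference of -3.41 points (permutation p = 0.00115). Every permutation test in this section shuffled genes measured in the same libraries. Its p therefore does not measure the spread between libraries or the effect of scaling. A partial effect of the introduced METTL16 in every cell, a biological alternative, was not tested and stays open.

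Small RNAs made up 47.2% of the calls between rescue and control but 2.76% of the genes tested. Of 16 with read estimates, 12 (75%) had fewer than 10 reads per library in the lower group, with a median of 2.75. Counting error on few reads may account for these calls, but the share under 10 reads was not compared with that of short RNAs not called. In simulated data 9 of 13 false calls in this comparison were short RNAs. The noise there came from the fitted spread and not from reads, so that count does not bear on counting error. A change in these RNAs with the METTL16 level, a biological explanation, was not tested.

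With the contrasts formed from separate libraries, 93.2% and 93.3% of the 1274 genes with the largest change in the first had the opposite sign in the second, against 49.9% in simulated tables where no group differed. The 21 tested genes within 1 Mb of METTL16 had a median log2 change of 0.050 in rescue against control (two-sided permutation test, p = 0.602) and 0.075 in knockout against control (permutation p = 0.911), and all tested genes had 0.061 and 0.067.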
